A study of Mus musculus with 19 samples.

How the data were processed

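Bulk RNA sequencing was done on sorted nasal epithelial cells of naive mice whose cholinergic cells carry enhanced green fluorescent protein (eGFP) from a transgene with the regulatory region of Chat. Per the labels, the tissue was digested with dispase and then papain, dead cells were excluded with propidium iodide, and cells were sorted by flow cytometry into lysis buffer. The 19 libraries fall into 3 groups: CD45-negative EpCAM-positive eGFP-positive cells of low scatter (FSClow, 9 libraries), the corresponding cells of high scatter (FSChi, 5 libraries) and EpCAM-positive eGFP-negative cells (EpCAM, 5 libraries). The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

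Per the submitters' processing notes, STAR 2.4.2a, Picard 1.1073, RSEM 1.2.21, featureCounts and DESeq2 were used with the mm10 build; the notes give these names without roles. The authors deposited a table of raw counts, whole numbers of reads per gene and library, for 27179 Entrez gene identifiers. The authors also deposited a normalized table with 26221 rows, here treated as a signal: each value is a count divided by a size factor of its library. When multiplied back, 100% of those values came out whole within a tolerance of 0.01, and all 26221 rows equalled a row of the count table. The deposited single-library files hold RSEM expected counts, which need not be whole, and, per the file headers, TPM, a unit scaled to gene length and library total. Expected counts were rounded before use.

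Gene symbols came from a RefSeq table for 25275 identifiers and from rows with identical counts in the normalized table for 582; the other 1322 kept their identifier and held 0.982% of counts. Coordinates are those of the RefSeq table, whose assembly is GRCm38.p6 (mm10), and are 1-based. The counting is not stated to use strand, so reads of overlapping genes may not be separable.

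The count table was analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and a robust quasi-likelihood model with group as its only term was fitted to all 19 libraries together. List counts cover only members that passed this filter, such as 9 of 38 taste receptor and 16 of 1126 olfactory receptor genes. Each of the 3 comparisons was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 are called higher or lower. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are given as CPM, read counts scaled to a common library total with TMM factors, as mean ± SD over libraries. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Library totals, detected genes and the shares of mitochondrial and ribosomal RNA were compared by two-sided exact permutation tests adjusted over 12 tests.

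The design, the 23 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined, with these exceptions. Mitochondrially encoded genes were later taken by chromosome in place of a symbol prefix. Kinase genes, pseudogenes and paralogous variants that share the prefix were later left out of the ribosomal protein list. The share of ribosomal RNA was later added to the library measures. The rule took, per comparison, the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 3 that were above 1 CPM in at least 75% of the libraries of the higher group, without predicted models. It also took up to 4 members of each list with the smallest p, of which the first 2 were followed through the alternatives, and 13 genes named in every comparison. The text names a part of the genes that the rule takes, and 1 that it takes is not reported here. A fold against a group without any count was computed against a floor of 3 counts over that group's libraries and is a lower bound; such floors and the intervals given with ratios (95%) cover counting error only.

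The model was tested on simulated counts with 200 changed genes, drawn from the means and library sizes of 13340 genes, of which 12980, 12948 and 13156 passed the filter in the simulations of the 3 comparisons. For FSClow against EpCAM, 31.4% of 2-fold, 83.9% of 4-fold and 95.6% of 8-fold changes were recovered. For FSChi against EpCAM these shares were 18.1%, 72.9% and 88.4%, and for FSChi against FSClow 17.2%, 68.8% and 94.4%. False calls made up 6.71%, 7.87% and 4.65% of calls in these simulations. Only the 200 genes changed there, in random directions, whereas 45.1%, 25.6% and 24.8% of tested genes were called in the data. The simulations therefore do not test the scaling or the error rate where many genes change unevenly.

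Alternatives covered relative log expression and upper-quartile scaling, other filters, DESeq2 1.42.0, voom with sample quality weights, a non-robust fit, RSEM expected counts, TPM on the log2(value + 1) scale with and without a minimum of 1 in 5 libraries and on the log2(value + 0.1) scale with it, the normalized table, fits of only the groups compared, replicate number as a block, a test against a fold change of 2, and leaving out each library. Alternatives chosen after seeing the data were thinning all libraries to the smallest total, removing the ribosomal RNA rows, RSEM counts without a file of few reads, only libraries whose table column matched its own file best, and reads recovered from the normalized table. The recovered reads called 2573 genes higher and 3282 lower in FSClow than in EpCAM, 1622 and 1750 in FSChi against EpCAM, and 2132 and 1133 in FSChi against FSClow.

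Each table column was correlated, across genes, with the expected counts of every single-library file. Of 19 columns, 14 matched the file of their own group and number best, with r from 0.961 to 0.972. The columns FSChi 3 and FSChi 4 matched the files FSChi 4 and FSChi 5 best (r = 0.970 and 0.967), FSChi 5 matched no file above r = 0.927, and EpCAM 1 and EpCAM 2 matched each other's files. The file FSChi 3 held 6807 expected counts over 1264 genes. It enters every fit on TPM values, and those on RSEM counts unless its removal is stated. Groups were never mixed, so the main results, which use the count table alone, do not depend on the numbering of files. No pair of libraries in a group agreed within sampling noise, the lowest chi-square per degree of freedom being 5.5 for FSClow replicates 1 and 2.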

Results

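Gene expression was measured by RNA sequencing in 19 libraries of sorted mouse nasal epithelial cells. Cholinergic cells, marked by eGFP under Chat regulatory sequences, were sorted into gates of low scatter (FSClow, n = 9) and high scatter (FSChi, n = 5) and set against eGFP-negative epithelial cells (EpCAM, n = 5). Total counts ranged from 1348428 in FSChi replicate 2 to 7477695 in FSChi replicate 3. FSClow libraries held fewer counts than EpCAM libraries, with means of 3097700 and 5478300 (exact permutation p = 0.0030, adjusted p = 0.018). Detected genes numbered 15157 ± 562 (SD, n = 9) in FSClow, 16267 ± 1920 (SD, n = 5) in FSChi and 18248 ± 163 (SD, n = 5) in EpCAM. Both eGFP-positive gates lay below EpCAM in this measure (exact permutation adjusted p = 0.012 and 0.032). The first principal component took 55.1% of the variance and placed FSChi libraries between the other groups.

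**Figure D1:**
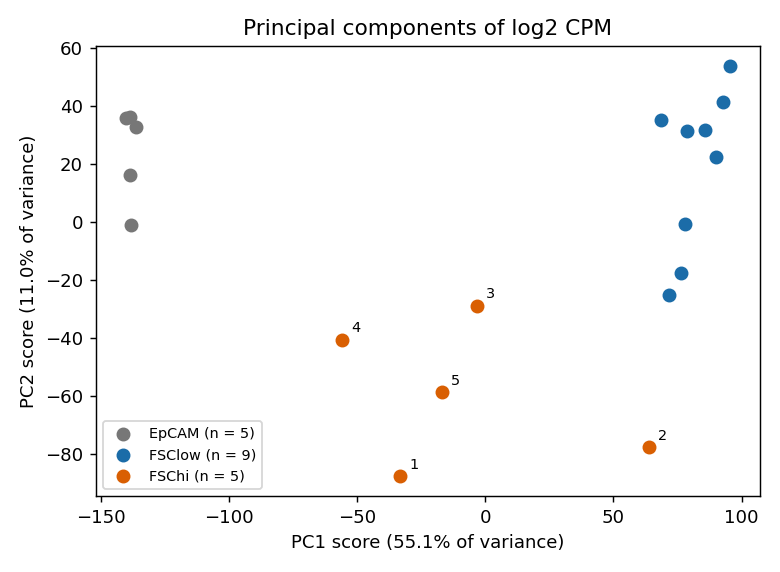
Scores of the 19 libraries on principal components 1 (55.1% of variance) and 2 (11%) of log2 CPM, one point per library, coloured by group, with FSChi replicates numbered. EpCAM libraries sit near -138 on component 1, while FSChi libraries spread from -55.9 to 63.8.

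The first comparison addressed how the cholinergic cells of low scatter differ from eGFP-negative epithelium. Genes of brush or tuft cells, the chemosensory epithelial cells to which cholinergic nasal cells belong, were far higher in FSClow. Chat, which makes acetylcholine (Entrez 12647, chromosome 14, 32408203 to 32465909, mm10), stood at 543 ± 55.0 CPM (SD, n = 9) in FSClow and 2.14 ± 1.15 CPM (SD, n = 5) in EpCAM, a log2 fold change of 8.0 ± 0.42 (SE, edgeR adjusted p = 5.4e-13). The sort on eGFP under Chat sequence selected for this gene. The cation channel gene Trpm5 (Entrez 56843, chromosome 7, 143071529 to 143094642) was higher by 10.14 ± 0.75 on the log2 scale (SE, edgeR adjusted p = 4.0e-10), or by 11.30 without EpCAM replicate 5. Il25, which encodes a cytokine of type 2 immunity (Entrez 140806, chromosome 14, 54932695 to 54935837), reached 2232 ± 1699 CPM in FSClow against 0.365 ± 0.597 CPM in EpCAM, with wide spread among FSClow libraries. Its log2 fold change was 12.47 ± 1.13 (SE), or 13.68 without EpCAM replicate 1. The transcription factor gene Pou2f3 was higher by 6.01 ± 0.35 (SE) on the log2 scale. Hmx3, a homeobox gene, had 3970 counts in FSClow and 2 in EpCAM, a ratio of 1958 (95% counting interval 541.7 to 16180), or of 3010 without EpCAM replicate 4 and 2980 without EpCAM replicate 5.

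Of 24 tested tuft and brush cell markers, 22 were higher and 1 was lower in FSClow (23 and 1 adjusted over the list alone), and camera called the list (adjusted p = 6.7e-48, and 2.8e-05 with an estimated correlation). Lrmp was higher by 8.81 ± 0.30 and Sh2d6 by 9.01 ± 0.37 on the log2 scale. Dclk1 stood at 136 ± 43.0 CPM in FSClow and 88.8 ± 16.9 CPM in EpCAM, which did not pass the test (edgeR adjusted p = 0.078). It passed without FSClow replicate 1 (adjusted p = 0.0324). Eicosanoid synthesis genes moved both ways, with 8 of 17 higher and 7 lower (8 and 7 adjusted over the list alone), and the list was called higher (camera adjusted p = 0.0012, and p = 0.034 with an estimated correlation). Its higher members included Alox5 by 8.87 ± 0.43, Alox5ap by 9.99 ± 0.58 and Ltc4s by 8.76 ± 0.41 on the log2 scale. Type 2 cytokine and receptor genes were called higher (6 of 8 higher, 2 lower, camera adjusted p = 0.00022, and p = 0.011 with an estimated correlation), with Il17rb higher by 7.32 ± 0.38 and Il4ra by 3.76 ± 0.31. Il17rb and Il25 of this list, and Alox5 and Ltc4s of the eicosanoid list, are also tuft list members. Calls of these lists therefore overlap in each comparison. P2ry2, a nucleotide receptor gene, was higher by 2.25 ± 0.31, whereas P2ry1 had 2 counts in FSClow and 578 in EpCAM, where it was higher by a ratio of 293 (95% counting interval 80.7 to 2425), or of 464 without FSClow replicate 8 and 527 without FSClow replicate 9. On the log2(TPM + 0.1) scale the call of P2ry2 ended (limma adjusted p = 0.0703). The purinergic receptor list itself, with 3 of 7 higher and 4 lower, was not called (camera adjusted p = 0.99).

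Taste receptor genes were called higher as a list (5 of 9 higher, 1 lower, camera adjusted p = 0.0051), a call lost with an estimated correlation (adjusted p = 0.27). The taste transduction list was likewise called (3 of 8 higher, 1 lower, camera adjusted p = 0.0079) and lost with an estimated correlation (adjusted p = 0.22). Tas2r138 had no count in EpCAM and was at least 136-fold higher in FSClow.

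Markers of other epithelial cells were lower in FSClow. Among single genes, the sodium channel gene Scn9a had a log2 fold change of -9.83 ± 0.76 and Stmn2 of -8.46 ± 0.78. All 18 olfactory sensory neuron markers were lower (camera adjusted p = 4.1e-12, but p = 0.14 with an estimated correlation), as were all 12 sustentacular cell markers (camera adjusted p = 2.0e-07, but p = 0.12 with an estimated correlation). Cnga2, a channel gene of olfactory neurons, was at 0.561 ± 1.26 CPM in FSClow and 282 ± 90.3 CPM in EpCAM, with a log2 fold change of -8.95 ± 0.81, or -10.55 without FSClow replicate 9. Basal cell markers were lower (10 of 12, camera adjusted p = 8.9e-07, and p = 0.034 with an estimated correlation), including Aqp3, with a log2 fold change of -6.68 ± 0.49. Secretory cell markers (15 of 19 lower, 1 higher), ciliated cell markers (12 of 13 lower), ionocyte markers (10 of 12 lower) and cell cycle genes (14 of 18 lower, 1 higher) were called lower by camera (adjusted p = 0.0051, 9.2e-05, 9.4e-05 and 0.0016), each call being lost with an estimated correlation (adjusted p = 0.34, 0.15, 0.28 and 0.28). Among ionocyte genes, the chloride channel gene Cftr had a log2 fold change of -3.43 ± 0.37. Sox9, listed with gland cell genes, went the other way, with a log2 fold change of 4.32 ± 0.30, as did Kit, listed with progenitor genes, at 2.41 ± 0.20. The Kit call ended on the log2(TPM + 0.1) scale (limma adjusted p = 0.158). MHC class II genes were called lower (4 of 8, camera adjusted p = 0.021), a call lost with an estimated correlation (adjusted p = 0.31).

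In all, 2931 genes were higher and 3086 lower in FSClow among 13340 tested. Relative log expression scaling gave a share of higher calls of 38.2% in place of 48.7%, and the share was 34.1% with DESeq2, 25.7% with the authors' normalized values and from 20.2% to 28.4% with TPM values. The former scaling put the median log2 fold change of all genes at -0.14 in place of 0.05, and for FSChi against EpCAM at -0.14 in place of -0.02. The lists of olfactory receptors, progenitor, leukocyte, stromal and pan-epithelial markers, early response genes, mitochondrially encoded genes and ribosomal proteins were not called (camera adjusted p = 0.95, 0.0503, 0.83, 0.20, 0.56, 0.95, 0.50 and 0.65), nor was acetylcholine synthesis and transport (adjusted p = 0.094). The olfactory receptor list had a median log2 fold change of -0.57 and a mean of -1.86 while its test pointed up. Without EpCAM replicate 5 it was called lower (adjusted p = 0.046), and the progenitor list was called lower without FSChi replicate 2, 4 or 5, FSClow replicate 6 or EpCAM replicate 5 (adjusted p = 0.0165, 0.018, 0.0278, 0.0422 and 0.046). The acetylcholine list was called higher without FSChi replicate 1 or 5 (adjusted p = 0.0358 and 0.0398). RSEM counts also called the acetylcholine and progenitor lists (adjusted p = 0.0244 for both). Fry, which does not set a list against the other genes, called the acetylcholine list higher (fry adjusted p = 9.1e-05). It called the progenitor and stromal lists lower (fry adjusted p = 3.6e-05 and 9.4e-05). Adjusted over the list alone, counts of higher and lower members became 4 and 7 of 16 olfactory receptors, 0 and 13 of 13 ciliated, 0 and 11 of 12 basal and 1 and 15 of 18 cell cycle genes. They became 7 and 5 of 20 early response genes in place of 6 and 4, none of 15 mitochondrial genes in place of 1 and 0, and none of 84 ribosomal protein genes in place of 1 and 5. The other lists, apart from the tuft and brush cell markers, kept their counts.

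The next comparison set the cholinergic cells of high scatter against the same EpCAM libraries. Of the tuft and brush cell markers, 23 of 24 were higher in FSChi (camera adjusted p = 8.6e-87, and p = 2.2e-06 with an estimated correlation). Chat was at 301 ± 92.0 CPM (SD, n = 5), higher than EpCAM by 7.15 ± 0.41 on the log2 scale (SE, edgeR adjusted p = 5.0e-12). Without EpCAM replicate 5 Trpm5 was higher by 10.75 in place of 9.58 ± 0.75, and without EpCAM replicate 1 Il25 was higher by 12.01 in place of 10.76 ± 1.09. Ltc4s was higher by 9.19 ± 0.42 and P2ry2 by 2.05 ± 0.33 on the log2 scale. The P2ry2 call ended with TPM values (limma adjusted p from 0.111 to 0.396). Gnat3, the taste G protein gene gustducin (Entrez 242851, chromosome 5, 17962570 to 18019668), reached 2109 ± 1089 CPM in FSChi and 1.72 ± 2.61 CPM in EpCAM, a log2 fold change of 10.17 ± 0.98 (SE, edgeR adjusted p = 2.0e-07), or 11.54 without EpCAM replicate 5.

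All 8 taste transduction genes and all 9 taste receptor genes tested were higher in FSChi than in EpCAM (camera adjusted p = 4.5e-13 and 2.2e-14, and p = 0.0041 for both with an estimated correlation). Of 38 taste receptor genes, only these 9 passed the filter. A gene nearly absent from EpCAM passes it only through eGFP-positive libraries, so these counts of higher members are partly set by the filter. The median log2 fold change of the receptors was 9.06, or 7.73 with genes at no count in EpCAM set to their bound. Tas2r138 had no count in EpCAM and was at least 901-fold higher in FSChi. Members of this receptor family are similar in sequence, so their single values are uncertain where reads could be shared. Eicosanoid synthesis (6 of 17 higher, 4 lower), type 2 cytokine and receptor (5 of 8 higher, 1 lower) and acetylcholine genes (3 of 6 higher, 1 lower) were called higher (camera adjusted p = 6.7e-06, 7.0e-05 and 0.00013), also with an estimated correlation (adjusted p = 0.0041, 0.0041 and 0.047). Slc18a3, the vesicular acetylcholine transporter gene, had no count in EpCAM and was at least 376-fold higher in FSChi. It lies inside the Chat interval, at 32462437 to 32464850 of chromosome 14, so reads of the 2 genes may not be separable without strand. The transgene carries sequence of this locus, and its transcripts, where made, are not separable from these counts. Because the sort on eGFP selected for Chat, the call of the acetylcholine list was partly set by the gate.

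Markers of eGFP-negative cell types were lower than in EpCAM, though present. Of the olfactory sensory neuron markers 11 of 18 were lower, of the sustentacular markers 10 of 12, of the basal markers 8 of 12, of the ionocyte markers 9 of 12, of the ciliated markers 4 of 13, and of the secretory markers 7 of 19 with 1 higher. Camera called these lists lower (adjusted p = 0.00017, 3.5e-05, 7.0e-05, 1.4e-05, 0.0065 and 0.046), and lost each call with an estimated correlation (adjusted p = 0.30, 0.13, 0.061, 0.12, 0.30 and 0.49). Cell cycle genes (5 of 18 lower, camera adjusted p = 0.0057) and, in the other direction, pan-epithelial genes (7 of 12 higher, 1 lower, camera adjusted p = 0.0099) and mitochondrially encoded genes (4 of 15 higher, camera adjusted p = 0.018) were called and lost in the same way (adjusted p = 0.25, 0.30 and 0.58). The secretory call ended without FSChi replicate 1, 2 or 5, without FSClow replicate 2, 4, 5, 7 or 8, without EpCAM replicate 3 or 4 (adjusted p from 0.0569 to 0.139) and with relative log expression scaling (adjusted p = 0.0966). The mitochondrial call ended without FSChi replicate 1 or EpCAM replicate 5 (adjusted p = 0.0928 and 0.0714), and the pan-epithelial call with RSEM counts (adjusted p = 0.138). Among single genes, the water channel gene Aqp3 had a log2 fold change of -3.30 ± 0.52, the kinase gene Sgk1 of -3.36 ± 0.51, Ahnak of -3.57 ± 0.67 and Cftr of -3.49 ± 0.46. Epcam itself was higher by 1.71 ± 0.24 on the log2 scale, a direction that turned on the log2(TPM + 1) scale (-0.43). The call ended with RSEM counts (adjusted p = 0.0512). The nearly empty FSChi 3 file enters both of these fits.

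In FSChi 1797 genes were higher and 1624 lower than in EpCAM, a share of higher calls of 52.5%, against 42.2% with DESeq2, 31.3% in the authors' normalized table and from 9.81% to 11.8% with TPM values. With only the libraries whose table column matched its own file, chosen after seeing the data, 1048 were higher and 790 lower. The purinergic, MHC class II, olfactory receptor, progenitor, leukocyte, stromal, early response and ribosomal protein lists were not called (camera adjusted p = 0.30, 0.16, 0.64, 0.20, 0.85, 0.47, 0.25 and 0.85). Of these, fry called the purinergic list higher and the MHC class II and progenitor lists lower (fry adjusted p = 0.0011, 0.037 and 0.024). Median, mean and test differed in sign for the purinergic list (-0.59, 0.86 and up), the olfactory receptors (-0.23, 0.01 and up) and the leukocyte list (-1.24, 1.06 and up). Adjusted over the list alone, higher and lower members numbered 3 and 2 of 6 acetylcholine, 6 and 5 of 17 eicosanoid, 5 and 2 of 8 type 2, 0 and 11 of 12 sustentacular, 0 and 9 of 12 basal and 0 and 12 of 12 ionocyte genes. They numbered 0 and 6 of 18 cell cycle and 8 and 0 of 15 mitochondrial genes, and, with the count over all genes after each, 2 and 5 of 8 progenitor (1 and 4), 1 and 1 of 3 leukocyte (1 and 0), 0 and 0 of 5 stromal (0 and 1), 0 and 4 of 20 early response (0 and 5) and 0 and 0 of 84 ribosomal protein genes (2 and 0). The other lists kept their counts.

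Both eGFP-positive gates shared 1434 genes higher and 1417 genes lower than in EpCAM, and 36 genes were called in opposite directions. Independent lists of the same sizes would share 394.8 higher and 375.7 lower genes. In 20 simulations of unchanged groups against the same EpCAM libraries 0 genes were shared, but independent lists of the genes called there would also share 0, so this sets no level for the overlap. With the EpCAM libraries split between the comparisons in 20 ways, the shared genes numbered from 718 to 929 higher and from 691 to 1159 lower. Independent lists of the sizes called in those splits would share 127.7 to 201.3 higher and 178.1 to 376.3 lower genes. Across genes, which are not independent replicates, the log2 fold changes of both comparisons had r = 0.773 and the same sign in 77.0% of genes, against means of 0.554 and 68.7% in the simulations. Their covariance was 2.46, against a mean of 0.109 in the simulations. The shared EpCAM libraries contribute to these values. With the EpCAM libraries split, r was 0.626 to 0.692, the same sign held in 64.9% to 77.0% of genes and the covariance was 2.59 to 2.76.

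**Figure D2:**
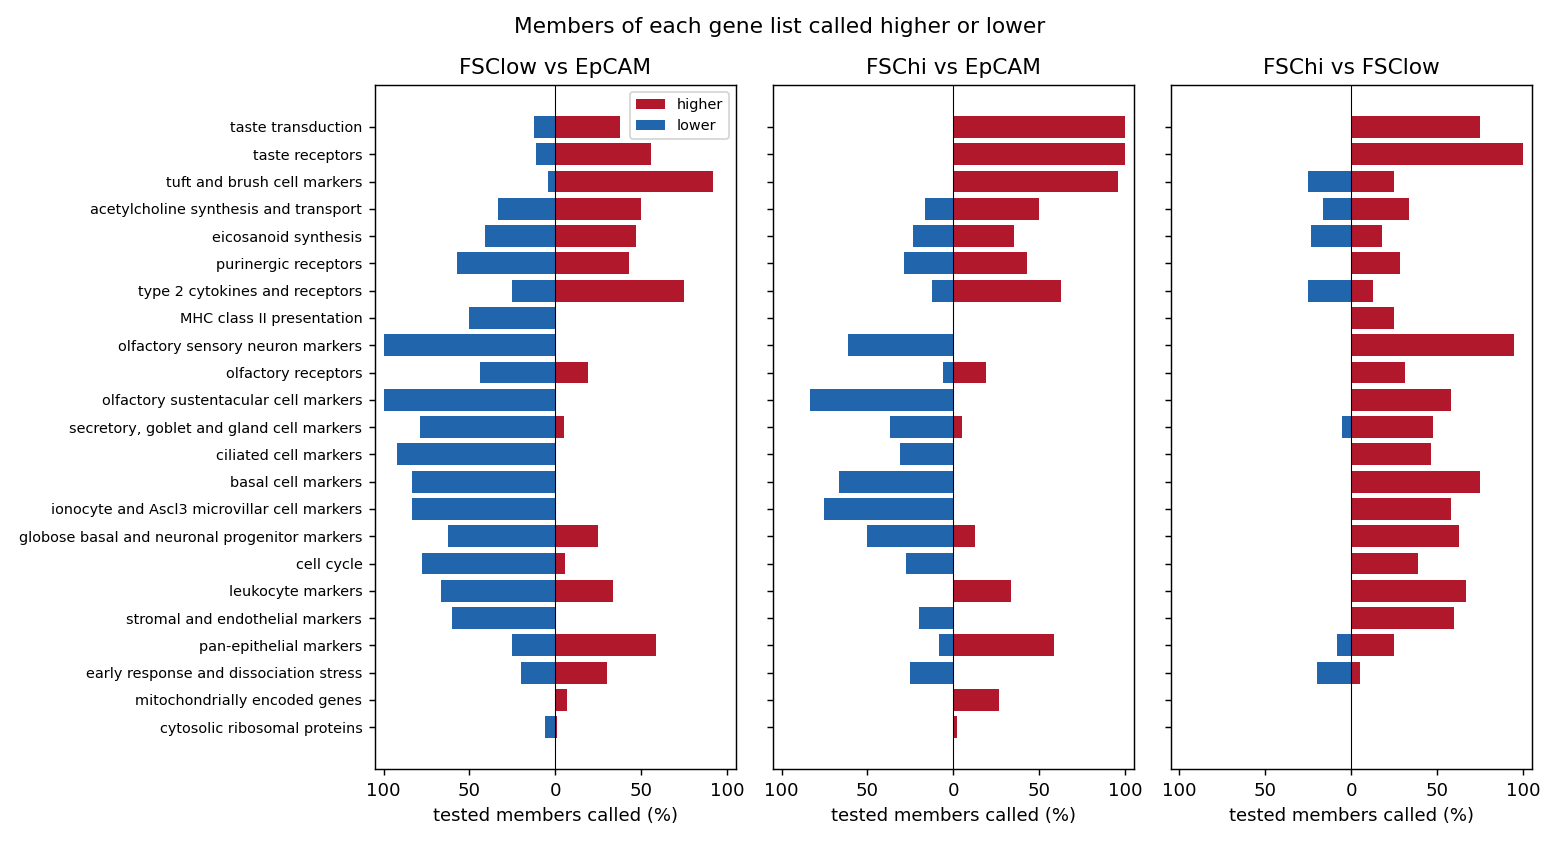
Share of tested members (%) of each gene list called higher (red, to the right) or lower (blue, to the left) in each of the 3 comparisons. All 9 taste receptor genes that passed the filter, of 38, were higher in FSChi than in either other group.

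The last comparison asked whether the profiles of the eGFP-positive gates differ from each other. Taste signalling genes were higher in FSChi: 6 of 8 taste transduction and 9 of 9 taste receptor genes (camera adjusted p = 1.4e-06 and 7.6e-11), calls that were lost with an estimated correlation (adjusted p = 0.14 and 0.096). A receptor gene present in FSChi alone passes the filter, so the count of 9 of 9 may be partly set by it. Gnb3, a G protein subunit gene of taste cells (Entrez 14695, chromosome 6, 124834240 to 124840275), was at 2178 ± 1194 CPM (SD, n = 5) in FSChi and 4.43 ± 4.26 CPM (SD, n = 9) in FSClow, a log2 fold change of 8.91 ± 0.73 (SE, edgeR adjusted p = 5.2e-08). Gnat3 was higher by 3.61 ± 0.58 (SE, edgeR adjusted p = 0.00011). With TPM values it was higher by 0.95 on the log2(TPM + 1) scale and 0.29 on the log2(TPM + 0.1) scale, which ended the call (limma adjusted p from 0.59 to 0.908). The nearly empty FSChi 3 file enters those fits. From the raw counts, Gnat3 was at 754.9 CPM or more in each FSChi library and at 257.8 CPM or less in each FSClow library. Tas2r105 was higher by 8.69 ± 0.74 (SE, edgeR adjusted p = 1.9e-07), or by 10.67 without FSClow replicate 6. Calhm1, a taste cell channel gene, had no count in FSClow and was at least 216-fold higher in FSChi. The keratin gene Krt19 (Entrez 16669, chromosome 11, 100140810 to 100145926) was at 909 ± 401 CPM in FSChi and 6.48 ± 4.83 CPM in FSClow, and Jakmip1 was higher by 6.37 ± 0.33 on the log2 scale.

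Tuft and brush cell markers went both ways between the gates. Of 24, 6 were higher and 6 lower in FSChi (6 and 7 adjusted over the list alone). The list was not called in 1 direction (camera adjusted p = 0.29) but changed in either direction (fry mixed adjusted p = 6.7e-16). Trpm5, Pou2f3 and Ltc4s had log2 fold changes of -0.56 ± 0.45, -0.35 ± 0.25 and 0.43 ± 0.23 and did not pass the test (edgeR adjusted p = 0.40, 0.34 and 0.18), though voom called Trpm5 and Pou2f3 lower (adjusted p = 0.0264 and 0.0286). Il25 was at 684 ± 310 CPM in FSChi and 2232 ± 1699 CPM in FSClow, which did not pass the test (edgeR adjusted p = 0.058). It passed without FSClow replicate 7 or EpCAM replicate 1, without robust estimation and after thinning (adjusted p = 0.0149, 0.0486, 0.0398 and 0.0484). Il25 also passed with replicate number as a block. Ptgs1, a prostaglandin synthesis gene, was lower in FSChi, with a log2 fold change of -1.55 ± 0.23 (SE, edgeR adjusted p = 2.2e-05), as were Il17rb at -1.15 ± 0.27 and Il13ra1 at -1.36 ± 0.33. With TPM values the calls of Il17rb and Il13ra1 ended on each scale (limma adjusted p from 0.108 to 0.238 and from 0.0516 to 0.108). That of Ptgs1 ended on the log2(TPM + 0.1) scale and without a filter (0.102 and 0.103). The test against a fold change of 2 ended the calls of Il17rb and Il13ra1 (adjusted p = 0.651 and 0.328), and only libraries matching their own file that of Il17rb (0.0852). The type 2 cytokine and receptor list was called lower (1 of 8 higher, 2 lower, or 1 and 6 adjusted over the list alone, camera adjusted p = 0.047), a call lost with an estimated correlation (adjusted p = 0.15) and without FSChi replicate 1, FSClow replicate 3 or FSClow replicate 8 (adjusted p = 0.0538, 0.0507 and 0.0598). The folate receptor gene Folr1 had a log2 fold change of -2.57 ± 0.43. The Schlafen family genes Slfn8, Slfn9 and Slfn10-ps, which are similar in sequence, had log2 fold changes of -2.24 ± 0.35, -2.38 ± 0.37 and -2.29 ± 0.41. Chat had a log2 fold change of -0.85 ± 0.28 (edgeR adjusted p = 0.028), a call that ended without FSChi replicate 1 (adjusted p = 0.095), FSChi replicate 4 (adjusted p = 0.074) or FSClow replicate 5 (adjusted p = 0.053). It also ended on the log2(TPM + 0.1) scale, on the log2(TPM + 1) scale without a filter, with the authors' normalized values and with only libraries matching their own file (adjusted p = 0.109, 0.114, 0.125 and 0.082). The test against a fold change of 2 and the replicate block ended it as well.

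**Figure D3:**
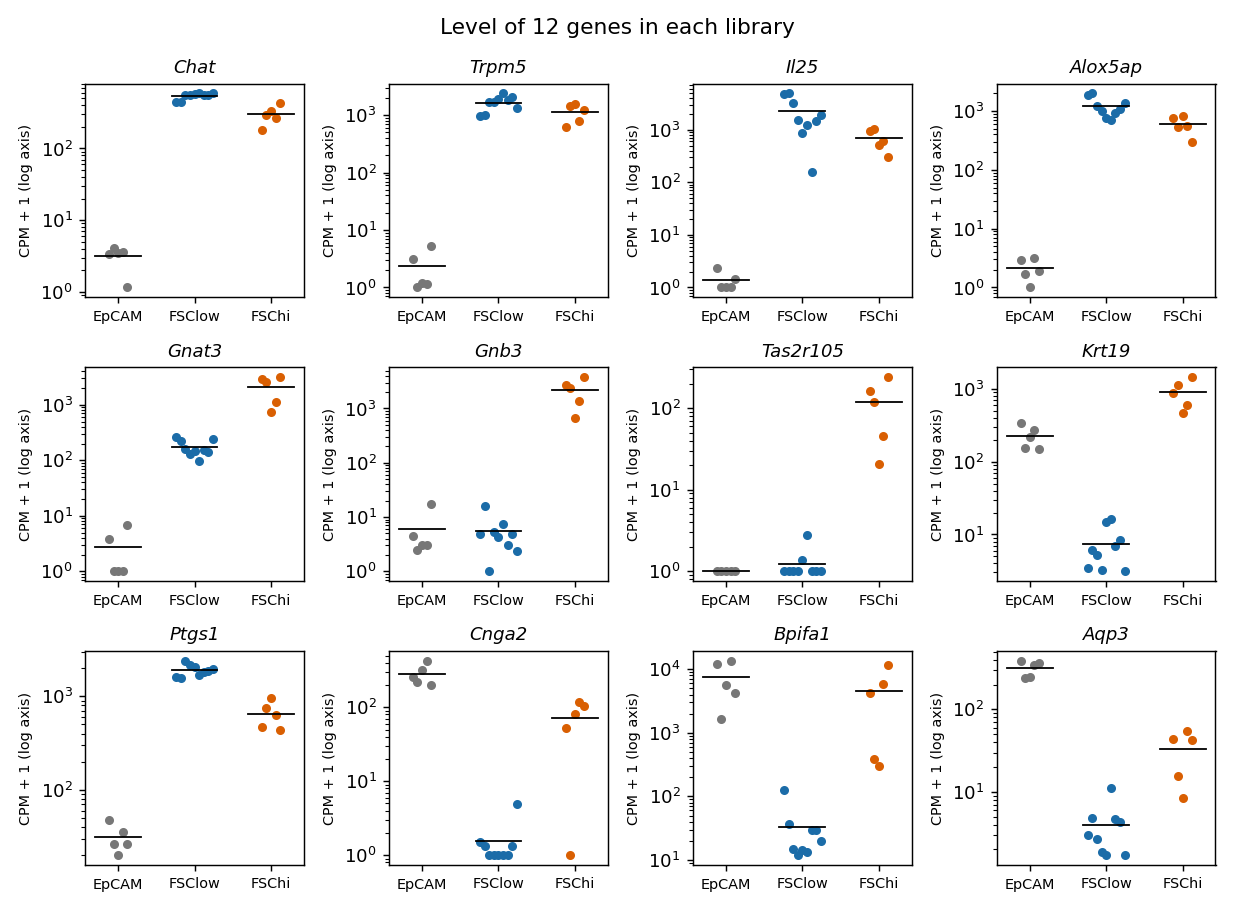
CPM + 1 on a log axis for 12 genes, one point per library and a line at each group mean (EpCAM n = 5, FSClow n = 9, FSChi n = 5). Gnb3 averaged 2178 CPM in FSChi and 4.43 CPM in FSClow.

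Markers of several eGFP-negative cell types were also higher in FSChi than in FSClow. Olfactory sensory neuron (17 of 18), sustentacular (7 of 12), ciliated (6 of 13) and basal cell markers (9 of 12) were called higher by camera (adjusted p = 3.9e-15, 0.00034, 0.0032 and 0.00015), calls lost with an estimated correlation (adjusted p = 0.14, 0.38, 0.38 and 0.14). The secretory list (9 of 19 higher, 1 lower) and the ionocyte list (7 of 12 higher) were not called (camera adjusted p = 0.073 and 0.29). Bpifa1, of the secretory list, was at 4465 ± 4661 CPM in FSChi and 31.8 ± 35.8 CPM in FSClow, and Cnga2 at 70.2 ± 46.4 CPM and 0.561 ± 1.26 CPM. The log2 fold change of Bpifa1 was 7.14 ± 0.89, or 6.46 without FSChi replicate 5 and 7.78 without FSClow replicate 1. That of Cnga2 was 6.96 ± 0.79, or 8.57 without FSClow replicate 9. Its call ended on the log2(TPM + 0.1) scale and without a filter on TPM values (limma adjusted p = 0.113 and 0.0998). These levels varied between FSChi libraries, and no count of Cnga2 was seen in FSChi replicate 2. On a scale from 0 at the FSClow mean to 1 at the EpCAM mean, the median olfactory neuron marker lay at 0.367, -0.0029, 0.223, 0.464 and 0.348 in FSChi replicates 1 to 5.

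**Figure D4:**
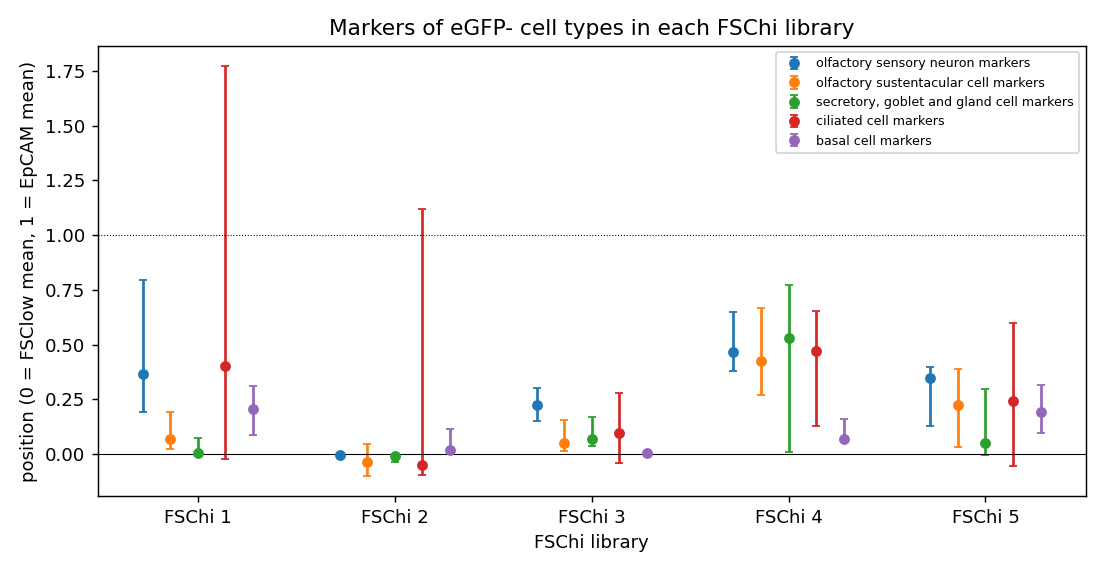
Median position of 5 classes of markers in each FSChi library on a scale from the FSClow mean (0) to the EpCAM mean (1), with 95% bootstrap intervals over markers. The intervals treat markers as independent and may be too narrow. The olfactory neuron class lies at 0.464 in FSChi replicate 4 and at -0.0029 in replicate 2.

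Between the gates 2069 genes were higher and 1241 lower in FSChi, and 761 of the higher but 3 of the lower ones differed by over 10-fold. The lower genes numbered 798 without FSChi replicate 4 and 808 without FSChi replicate 1, and a fit of only the groups compared gave 1179 higher genes. The share of higher calls was 62.5%, against 73.1% in the authors' normalized table. With TPM values, which include the nearly empty FSChi 3 file, the balance turned. The shares were 32.8% on the log2(TPM + 1) scale, 45.2% on that scale without a filter and 49.6% on the log2(TPM + 0.1) scale. The secretory, ionocyte, progenitor, cell cycle, leukocyte, stromal, pan-epithelial, MHC class II, olfactory receptor, purinergic, acetylcholine, eicosanoid, early response, mitochondrially encoded and ribosomal protein lists were not called (camera adjusted p = 0.073, 0.29, 0.073, 0.078, 0.49, 0.20, 0.11, 0.073, 0.61, 0.29, 0.29, 0.55, 0.095, 0.12 and 0.49). Several of these were called when 1 library was left out: MHC class II without FSClow replicate 1, 2 or 7 (adjusted p = 0.0451, 0.0341 and 0.0455), secretory without FSChi replicate 2 or FSClow replicate 1 (0.0178 and 0.0193), progenitor without FSChi replicate 2 or 5 (0.00967 and 0.00824) and cell cycle without FSChi replicate 5 (0.00559). The same held for the stromal list without FSChi replicate 2 (0.0449), early response without FSClow replicate 7 (0.00181) and mitochondrial genes without FSClow replicate 2 (0.0467). RSEM counts called the MHC class II, secretory, ionocyte, progenitor, cell cycle and early response lists (adjusted p = 0.0249, 0.017, 0.0238, 0.00789, 0.00164 and 0.00952). With fry, the secretory, progenitor, cell cycle, leukocyte, stromal, pan-epithelial, MHC class II, purinergic and acetylcholine lists were called higher (fry adjusted p from 0.0024 to 0.042). Median, mean and test differed in sign for the acetylcholine (-0.69, 0.79 and up) and eicosanoid lists (0.09, 0.13 and down). Adjusted over the list alone, higher and lower members became 8 and 0 of 12 sustentacular, 10 and 0 of 12 basal, 8 and 0 of 18 cell cycle (7 and 0 over all genes) and 3 and 1 of 5 stromal genes (3 and 0 over all genes). The other lists, apart from the tuft and type 2 lists, kept their counts.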

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

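The tests of eGFP-negative cells in a shared or in differing proportions, of such cells as the source of the taste genes, and of depth for the balance of increases were chosen after the result was seen.

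Of 100 splits of the libraries of each pair of groups only 1, the real one, called as many genes. This argues against a random division of these libraries as the source of the differences. Libraries of a group may not come from separate animals, so the splits cannot exclude chance between animals. In fits of the groups compared, the real split called 5663 genes between FSClow and EpCAM against at most 898 in the other splits. For FSChi against EpCAM it called 3514 genes against at most 3, and for FSChi against FSClow 2106 against at most 999.

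The first pattern is the higher level of markers of eGFP-negative cell types in FSChi than in FSClow, with 48 markers of 5 classes called, of which Gng8 is also in the progenitor list. Against 1 shared proportion of eGFP-negative cells, the classes lay apart beyond their 95% intervals in 3 of 5 FSChi libraries. In replicate 4, olfactory neuron markers lay at 0.464 (interval 0.38 to 0.649) and basal markers at 0.0701 (interval 0.0595 to 0.16) of the way from FSClow to EpCAM. The intervals resample markers within 1 library as if independent, though markers of a class are correlated (estimated 0.69 for olfactory neuron and 0.18 for basal markers). They may be too narrow, and the many pairs of classes were compared without adjustment, so these positions argue only weakly against 1 shared proportion. Library depth was argued against by thinning, after which 95.8% of these markers were still called. Such cells or their RNA in proportions that differ by type and library cannot be told apart from weaker expression by eGFP-positive cells of high scatter. Levels against EpCAM do not separate these sources, since either could leave the markers below EpCAM. Of the 48 markers, 47 had a lower mean in FSChi than in EpCAM, and 0% were called higher. Bpifa1 stood at 4465 CPM and Cnga2 at 70.2 CPM in FSChi.

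The second pattern is the higher level of taste receptor and taste transduction genes in FSChi, with 15 members called. Of these members 100% were also called higher in FSChi than in EpCAM. All tested members of both lists were higher there, so this share was known in advance and is no separate test. The filter also partly set which members were tested. The levels themselves argue against admixed cells of the mix in the EpCAM libraries, which would not lift a gene above its level there. Gnb3 stood at 2398 CPM in FSChi replicate 2, where olfactory neuron markers lay at -0.0029 of the way to EpCAM. Depth was argued against by thinning, which left 73.3% of the members called. A difference between eGFP-positive cells of the gates and, for the receptor genes, reads shared among family members stay open and were not tested.

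The third pattern is the balance between the gates, where 761 increases but 3 decreases in FSChi exceeded 10-fold, though with TPM values, which include a nearly empty FSChi file, only 32.8% to 49.6% of calls were higher. Depth as the whole cause was argued against, since 61.7% of the genes called after thinning were higher. Of the genes higher by over 10-fold, 85.6% had a lower mean in FSChi than in EpCAM. Cells or RNA of eGFP-negative types could leave them so, but so could weaker expression by eGFP-positive cells, and this share favours neither. The other genes include 71 called higher in FSChi than in EpCAM, which cells of the mix in the EpCAM libraries would not bring. No test separated a change of the eGFP-positive cells themselves from admixture for the rest.

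Single libraries stood apart in 31 of 325 tests, where chance gives about 1 in 20 if values are normal and independent. Genes of a cell type vary together and some had no count in a library, so that rate sets no level here. FSChi replicate 2 also had the smallest total, 1348428 counts. The values that follow are the gap to the nearest library over the range of the group. FSChi replicate 2 was lowest for Adora2b (0.714), Ano2 (0.862), Cnga2 (0.804), Cntn4 (0.784), Fstl5 (0.905), Lypd2 (0.718), Mslnl (0.836), Nr4a3 (0.8245) and Rtp2 (0.721). FSChi replicate 4 was highest for Cd74 (0.769), Olfr611 (0.932) and Olfr681 (0.946), and FSChi replicate 5 lowest for Fosb (0.718). FSClow replicate 1 was highest for Bpifa1 (0.532), Bpifb4 (0.768), Bpifb6 (0.787) and Rtn1 (0.717). FSClow replicate 8 was highest in total counts (0.557) and Ebf2 (0.685), and FSClow replicate 6 in Aqp3 (0.501). FSClow replicate 7 was lowest for Fosb (0.705) and Nr4a3 (0.664), and FSClow replicate 2 for Ccdc39 (0.751). EpCAM replicate 5 was lowest for Chat (0.819) and P2ry2 (0.733) and highest for Gnb3 (0.7135), Rplp0 (0.7495) and Rps4l (0.790). EpCAM replicate 3 was lowest for Dcn (0.722) and Il17rb (0.773), and EpCAM replicate 1 for Olfr611 (0.730).

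Of the genes named, 2 were called in opposite directions against EpCAM in the gates, and edgeR called the difference between the gates itself. Krt19 had log2 fold changes of -5.11 in FSClow and 1.99 in FSChi, a difference of 7.105. Slc44a4 had log2 fold changes of -2.14 in FSClow and 1.94 in FSChi, a difference of 4.08.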

How the results depend on the processing

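The settings chosen after the data were seen were thinning, removal of ribosomal RNA, RSEM counts without the file of few reads, only libraries whose column matched its own file, and recovered reads. For lists, 1518 values under other settings kept direction and side of the threshold, 43 gained a call, 42 lost it and 50 turned direction. For named genes these numbers were 7104, 42, 350 and 23. Fry ended no list call that camera made at the preset correlation, including those lost with an estimated correlation, and added 15. It asks whether the members change, not whether they change more than other genes. The cause was not tested where no construction is named. Counts of called genes within 1.5 times of the reported ones are not repeated here. Depth limits the calls: thinned to the smallest total, 2243 genes were higher and 2262 lower in FSClow than in EpCAM, 1392 and 1314 in FSChi against EpCAM, and 1546 and 958 in FSChi against FSClow.

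Genes lower in FSClow than in EpCAM (3086) numbered 5152 without a filter, which tests more genes, and 4801 with DESeq2. With voom, 2659 genes were lower in FSChi than in EpCAM (1624) and 2265 lower in both gates (1417). RSEM counts gave 1167 genes higher in FSChi than in EpCAM (1797) and 809 lower in FSChi than in FSClow (1241). Without the file of few reads these were 1568 and 806. The authors' normalized values gave 5756 genes lower in FSClow and 3216 lower in FSChi than in EpCAM, 2906 lower in both, and 762 lower in FSChi than in FSClow. A fit of only the groups compared gave 1179 genes higher in FSChi than in FSClow (2069).

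On the log2(TPM + 1) scale, on the log2(TPM + 0.1) scale, and on the former without a filter, genes higher in FSClow than in EpCAM (2931) numbered 1009, 577 and 902. Those higher in FSChi than in EpCAM numbered 264, 190 and 269, and those higher in both gates (1434) 192, 152 and 173. Those higher in FSChi than in FSClow numbered 326, 168 and 165, and those lower 667, 171 and 200. Without a filter 2473 were lower in FSChi than in EpCAM and 2198 lower in both. The nearly empty FSChi 3 file enters these TPM fits.

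Against a fold change of 2, a stricter test by construction, 1044 genes were higher and 2029 lower in FSClow than in EpCAM, 693 and 446 in FSChi against EpCAM, 1068 and 69 in FSChi against FSClow, and 561 and 421 in both gates. With only libraries whose column matched its own file, and so fewer libraries, 1048 were higher and 790 lower in FSChi than in EpCAM, 1331 and 423 in FSChi against FSClow, and 823 and 648 in both gates. Leaving out each library gave 2295 to 3117 genes higher and 2972 to 3533 lower in FSClow than in EpCAM, and 1384 to 1882 and 1318 to 1858 in FSChi against EpCAM. It gave 1836 to 2229 higher and 798 to 1350 lower in FSChi than in FSClow.

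Directions of named genes turned with TPM values. On the log2(TPM + 1) scale, with or without a filter, log2 fold changes for FSChi against EpCAM were -0.43 for Epcam, -0.13 for Rps4l and -1.43 for Rps24. On the log2(TPM + 0.1) scale they were -1.09, -0.77 and -2.09, with -0.19 for Cldn7 and -0.29 for Dclk1. For FSChi against FSClow they were -0.23 for Dclk1, -0.83 for Rpl39 and -1.53 for Ltc4s on the former scale. On the latter they were -0.88, -1.48 and -2.20, with -0.18 for Gstm2. Olfr611 turned to -3.24 with only the libraries matching their own file, and ranged from -1.68 to 4.38 on leaving out each library. Genes detected in FSChi minus FSClow came to -1660 with RSEM counts (exact permutation p = 0.668). The FSChi 3 file held 1264 genes, the other FSChi files 13126 to 18832 and FSClow files 14733 to 16865.

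Lists that turned direction were uncalled in each case but 1. For FSClow against EpCAM, the adjusted p of the purinergic list was 0.908 with relative log expression scaling and 0.722 to 0.994 on leaving out each library. With fry it was 0.893 for olfactory receptors and 0.976 for early response genes. On leaving out each library these lists gave 0.0460 to 0.998 and 0.438 to 0.994, the olfactory receptors being called lower without EpCAM replicate 5. Ribosomal protein genes gave 0.202 to 0.944. For FSChi against EpCAM, fry gave 0.989 for ribosomal protein genes, and leaving out each library 0.1401 to 0.952 for these and 0.1401 to 0.9997 for olfactory receptors. For FSChi against FSClow, ribosomal protein genes gave 0.385 with RSEM counts and 0.0781 to 0.993 on leaving out each library.

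Replicate numbers of the count table did not meet the rule for pairing, that every pair of the same number correlate above 0.1 in deviations from the group means. In each comparison 1 of 5 pairs did. The rule cannot exclude that some of the libraries are paired. The correlations ran from -0.192 to 0.17 for FSClow and EpCAM, from -0.0493 to 0.254 for FSChi and EpCAM, and from -0.0988 to 0.404 for FSChi and FSClow. Of 5 libraries, 0, 2 and 1 correlated best with their own number. These numbers differ from those of the single-library files for 5 libraries, and which are right was not settled. With the file numbers, a check chosen after the data were seen, 1 of 5, 3 of 4 and 2 of 4 pairs were above 0.1, so not every pair was in any comparison (lowest r -0.192, 0.0211 and -0.0988). By count table numbers, pairs of the same number averaged -0.031, 0.053 and 0.062, and pairs of other numbers 0.0046, -0.013 and -0.0075. Some pairs of other numbers were higher: FSChi 1 with FSClow 2 and 9 (0.369 and 0.193), and EpCAM 5 with FSClow 1, 2 and 9 (0.267, 0.281 and 0.218). Whether such libraries share a batch, which the model of group alone would ignore, was not tested. With the replicate block, 2318 genes were higher and 2861 lower in FSClow than in EpCAM, 1612 and 1659 in FSChi against EpCAM, and 1398 and 584 in FSChi against FSClow. The block turned the purinergic list in FSClow against EpCAM (adjusted p = 0.669) and the ribosomal protein list in each comparison (adjusted p = 0.907, 0.959 and 0.734). It called the progenitor list in FSClow against EpCAM (adjusted p = 0.048) and early response genes in FSChi against FSClow (adjusted p = 0.00038), and changed no other list call. In FSChi against FSClow it called Il25 (adjusted p = 0.00596) and ended the calls of Chat and Olfr611 (adjusted p = 0.166 and 0.082), and in FSChi against EpCAM that of Rps24 (adjusted p = 0.0608), among other named genes.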

Other observations

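No test in this part was chosen after the result was seen, and the genes were taken by the rule stated for named genes.

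Ptprc encodes CD45, the surface protein by which leukocytes were excluded in sorting. It had no count in any EpCAM library and was present in all 14 eGFP-positive libraries, at 12.5 ± 9.38 CPM (SD, n = 9) in FSClow and 6.90 ± 6.40 CPM (SD, n = 5) in FSChi, where replicate 3 had 18.0 CPM and the others from 2.61 to 6.43 CPM. It was at least 130-fold higher in FSClow and at least 79.1-fold higher in FSChi (edgeR adjusted p = 7.6e-07 and 1.8e-05), or at least 31.7-fold in FSChi without replicate 3. With TPM values the FSChi call ended (limma adjusted p from 0.0751 to 0.255). The leukocyte list, with 3 genes tested, was not called in either gate (camera adjusted p = 0.83 and 0.85). Fyb, an adaptor protein gene, stood at 524 ± 99.4 CPM in FSClow and 0.196 ± 0.439 CPM in EpCAM. Its log2 fold changes were 11.26 ± 0.57 in FSClow and 10.03 ± 0.56 in FSChi, or 14 and 12.79 without EpCAM replicate 1. Vav1, a signalling gene, was higher by 9.92 ± 0.72 in FSClow. Lyz2 and Coro1a, listed with leukocyte genes, went the other way in FSClow, with log2 fold changes of -7.99 ± 1.26 (-8.79 without FSClow replicate 6) and -3.80 ± 0.74.

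Olfr461, of the olfactory receptor family, was higher in both eGFP-positive gates. It stood at 29.7 ± 10.5 CPM in FSClow, 61.8 ± 27.8 CPM in FSChi and 0.196 ± 0.439 CPM in EpCAM, with log2 fold changes of 7.12 ± 0.62 and 8.16 ± 0.65. Without EpCAM replicate 1 these were 9.86 and 10.92. Adora1, an adenosine receptor gene, was higher by 6.25 ± 0.42 in FSClow and by 5.65 ± 0.43 in FSChi. Of early response genes, Fosb was higher by 1.67 ± 0.33 in FSClow than in EpCAM and had a log2 fold change of -1.86 ± 0.33 in FSChi against FSClow, while Socs3 had one of -3.57 ± 0.52 in FSClow against EpCAM. With TPM values the calls of Fosb ended in FSClow against EpCAM (limma adjusted p from 0.282 to 0.613) and, on the log2(TPM + 0.1) scale and without a filter, in FSChi against FSClow (0.0936 and 0.078). Receptor genes of the olfactory family are similar in sequence, so reads of Olfr461 may be shared with other members, which was not tested.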
